A study of Homo sapiens with 12 samples.

How the data were processed

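The data are gene counts from RNA sequencing of AsPC-1 cells in 12 libraries, 3 each of siBACH1, siCont, sgBACH1 and sgCont, grouped by the sample titles. Per the labels' protocols, siRNA was transfected 24 h before harvest, and knockout cells were made with the lentiCRISPR v2 vector and selected in 10 µg/ml puromycin. Total RNA was depleted of rRNA, made into libraries with an Ion Total RNA-seq kit and sequenced on an Ion Proton, a single-end instrument with short fragments of uneven length. The knockout guide is CCACTCAAGAATCGTAGGCCAGG with its AGG motif at the end. It matched chromosome 21 from 29321457 to 29321479 on the plus strand (GRCh38), in coding exon 2 of 5 of *BACH1*, and Cas9 is taken to cut after codon 65 of 736. The sequence of the siRNA is not given in the sources used here, nor is the control guide.

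The deposited values are raw read counts per gene in 1 table per experiment, and per the submitters' processing notes the authors used HTSeq 0.9.1 and SAMtools with genome hg19. The aligner, the counting mode and whether counting used strand are not given in the sources used here. HTSeq by default discards reads that map to several places or overlap several genes, which in that mode would lower counts of genes with near-identical copies, and rRNA depletion keeps nuclear and unspliced RNA in the counts. HTSeq's totals of unassigned reads are not among the values used here, so depth is the sum over genes, from 13099706 to 21478886 counts per library. The tables hold 57820 gene identifiers, and every column matched a sample. By identifier 51996 took a symbol from a reference of current gene names, and others took the GENCODE 29 name where there was one. The 3′ UTRs and coordinates come from the GENCODE 29 annotation on GRCh38 and were never set against hg19 coordinates.

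Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter with a minimum count of 10, and the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, called at an adjusted p below 0.05. Each experiment was fitted alone without a replicate block, and the difference of the responses was tested in 1 fit of 12 libraries with 4 group means. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts scaled to a common library size by TMM, and CPM summed over a list are scaled by library totals alone. The exact permutation test of *BACH1* was two-sided on log2 values with 1 count added. Where a group stood at 0 counts the fold is a bound against 3 counts over the group. Genes called in both experiments were compared with independent lists and by one-sided Fisher's exact tests. The experiments share no control libraries.

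Gene lists were fixed before the data were examined, as were the groups, the tests of the comparisons and the alternatives below that are not said to be added. List tests of the difference were not in that plan. There are 24 lists: heme and iron, antioxidant, BACH1 relatives and partners, epithelial, mesenchymal, glycolysis, hypoxia, integrated stress and unfolded protein response, cholesterol, cell cycle, p53 and DNA damage, interferon, NF-kB and cytokines, heat shock, pancreatic ductal, acinar and endocrine, fibroblast, blood and endothelium, neighbours of *BACH1* on chromosome 21, mitochondrially encoded, nuclear respiratory chain, ribosomal protein, histone, and abundant noncoding RNA. Lists with at least 5 tested members were tested with camera (limma 3.58.1; preset correlation 0.01, Benjamini-Hochberg over the lists), beside an estimated correlation and fry. With the estimated correlation the antioxidant list kept its call in both experiments, and the heme and iron, ductal, mesenchymal and cholesterol lists did so in the knockout.

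The genes named for each comparison were chosen by rule. Per experiment they are *BACH1* and the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1, separated groups and a proper gene symbol. For both experiments together they are the 12 with the largest smaller change, and for the difference the 6 largest each way, where separation of groups has no meaning and was not asked. Members of the lists may also be named, mainly the 4 with the largest called changes. Some genes that these rules select are not reported here. Of 58 such genes, 14 overlap an exon of a gene on the opposite strand (among them *BACH1*, *BCAS1*, *CEMIP*, *FAM83A*, *GUCY2C*, *IQGAP2*, *KCNE3*, *LDLRAD4*, *MUC5B* and *PAQR3*) and 5 overlap a gene on their own strand (among them *BACH1*, *CEACAM5*, *CFI* and *MISP3*), so their counts are uncertain.

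The edgeR steps were tested on simulated counts with 200 changed genes. Changes of 1.5, 2 and 4 fold were recovered in 34.3%, 80.6% and 97.0% of genes for the siRNA comparison (14591 genes), in 53.7%, 83.6% and 93.9% for the knockout (14469 genes) and in 16.4%, 58.2% and 81.8% for the difference (15644 genes). The share of false calls was 7.2%, 3.8% and 7.1%. The biological coefficient of variation was 0.144 with the siRNA, 0.159 in the knockout and 0.155 over 12 libraries.

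Alternatives were RLE, upper quartile and library-total scaling, no low-count filter and a stricter one, DESeq2 1.42.0, limma-voom, other estimates of the spread, a replicate block, leaving out mitochondrial and structural RNAs, an adjusted p of 0.1, and leaving out each library. After seeing the data, offsets for GC content and length (loess span 0.3) and fits without genes carrying a 3′ UTR match or lying in moved chromosome blocks were added. The 7-base sequences were scored by regression of log2 fold change over genes on the presence of each sequence in the 3′ UTR. The regression was adjusted for log 3′ UTR length and its square, 3′ UTR GC content and its square, and mean log2 CPM. The score is the coefficient over its standard error. Tested genes were grouped by GRCh38 position into windows of about 100 genes, and their medians were set against 1000 shuffles of the gene order. Called genes were also set against the median of every second gene of their window, with the gene not among those, and against the 10 nearest tested genes on each side, also asking whether these moved by at least 0.5 times as much, with 2 genes on each side as a narrower measure. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps. No pair of replicates was close enough to be 1 library deposited again.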

Results

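RNA was measured in AsPC-1, an established human pancreatic ductal adenocarcinoma cell line, by sequencing rRNA-depleted total RNA in 12 libraries. They fall into 4 groups of 3. SiBACH1 cells were harvested 24 h after transfection with a small interfering RNA (siRNA) against *BACH1*, and siCont cells are the controls of that experiment. SgBACH1 cells had been infected with a lentivirus carrying Cas9 and a guide RNA against *BACH1* and selected with puromycin, and sgCont cells are their controls. *BACH1* encodes a heme-binding transcriptional repressor that represses antioxidant and heme-breakdown genes at the DNA sites used by the activator NRF2. Replicates 1 to 3 held 16451523, 19975339 and 21478886 counts in siBACH1 and 14239837, 13099706 and 16546863 in siCont. They held 16535594, 16088094 and 20624435 counts in sgBACH1 and 18773195, 14107198 and 17258291 in sgCont. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

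*BACH1* itself (ENSG00000156273.11, chromosome 21) stood at 24.9, 27.7 and 24.7 CPM (counts scaled to a common library size) in siBACH1 and at 196.9, 293.7 and 196.5 CPM in siCont. The means were 25.8 ± 1.69 and 229.1 ± 56.0 CPM (SD, n = 3 each), a log2 fold change of -3.15 ± 0.17 (SE; edgeR adjusted p = 4.09e-06). In the knockout experiment *BACH1* stood at 218.3, 198.1 and 185.3 CPM in sgBACH1 and at 267.8, 293.7 and 276.4 CPM in sgCont. The means were 200.6 ± 16.6 and 279.3 ± 13.2 CPM (SD, n = 3 each), a log2 fold change of -0.48 ± 0.08 (SE; edgeR adjusted p = 4.48e-05). The groups did not overlap in either experiment, and a two-sided exact permutation test gave p = 0.1 in each, the smallest p that 3 against 3 libraries allow. Counts over the whole gene do not measure protein: the guide matches coding exon 2 of 5 and its cut site lies after codon 65 of 736, so edited transcripts can still be counted.

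**Figure D1:**
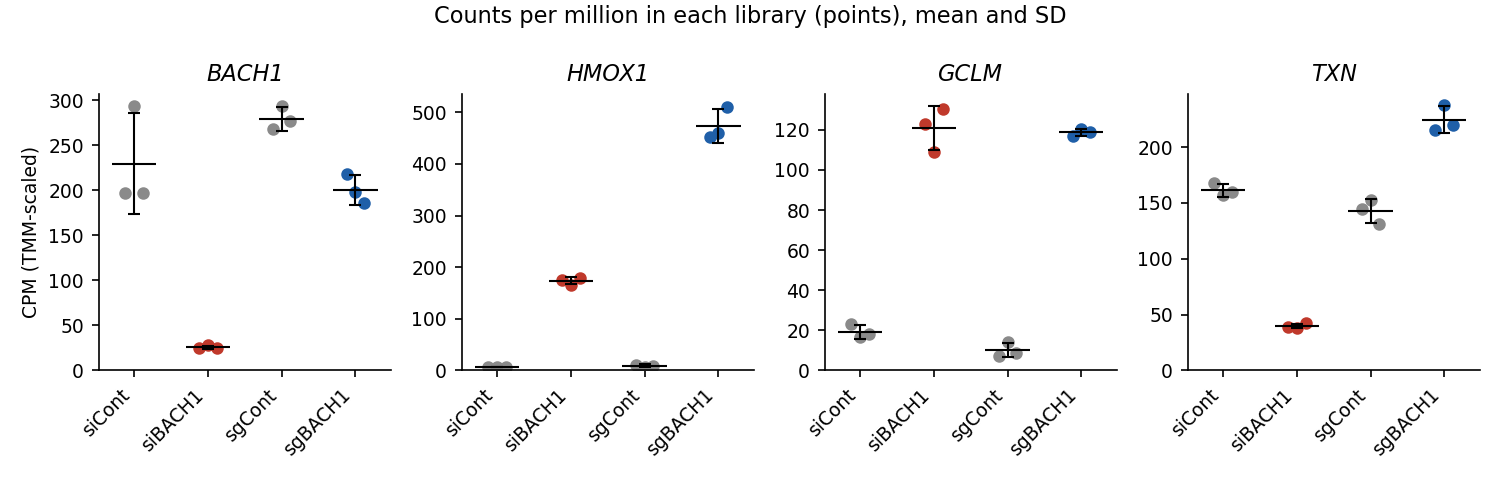
CPM (TMM-scaled) of *BACH1*, *HMOX1*, *GCLM* and *TXN* in each library (points) of siCont, siBACH1, sgCont and sgBACH1, with the mean (line) and SD (bar) of the 3 libraries. *HMOX1* and *GCLM* were higher in both siBACH1 and sgBACH1 than in their controls, while *TXN* was lower in siBACH1 (39.8 against 161.2 CPM) and higher in sgBACH1 (224.3 against 142.5 CPM).

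The siRNA comparison asks which genes respond when BACH1 is lowered, the study's way of searching for genes under its control and for its part in epithelial-mesenchymal transition. *HMOX1* (ENSG00000100292.12, chromosome 22), which encodes the heme-degrading enzyme heme oxygenase 1, rose most among the named genes, from 6.63 ± 0.568 to 173.6 ± 7.12 CPM (SD, n = 3 each; 26.1-fold, log2 4.70 ± 0.10 SE, edgeR adjusted p = 4.31e-08). *GCLM* (ENSG00000023909.5, chromosome 1), the modifier subunit of the enzyme that begins glutathione synthesis, rose from 19.4 ± 3.47 to 120.9 ± 11.0 CPM (SD, n = 3 each; log2 2.64 ± 0.14 SE, edgeR adjusted p = 3.81e-06). *ALDH1A1*, a retinaldehyde-oxidising enzyme, rose by 2.53 ± 0.16 on the log2 scale (SE). *TGFBR1*, the type I receptor for transforming growth factor beta, fell by 2.67 ± 0.17, and *SNAI2*, a repressor of epithelial genes, fell by 2.16 ± 0.18 (SE, edgeR adjusted p = 4.93e-05). *TXN*, thioredoxin, fell by 2.02 ± 0.08 (edgeR adjusted p = 2.18e-06).

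Of 14591 genes tested by edgeR, 3481 changed at an adjusted p below 0.05 in siBACH1, 1586 of them upwards and 1895 downwards. Which direction held more genes depended on the scaling, with 1820 upwards and 1757 downwards by upper quartile scaling, and 1821 and 1720 with offsets for GC content and length, a fit added after seeing the data. By more than 1 on the log2 scale 233 rose and 636 fell. The libraries of the groups did not overlap in 6200 genes (42.5%), where chance gives 10%. Without siBACH1 replicate 1, 2 or 3 edgeR called 2002, 2078 or 2096 genes, and without genes carrying a 3′ UTR sequence given below it called 2071, a fit added after seeing the data. Other large rises with separated groups, several of them from low counts, were *BCAS1* (log2 3.45), *CEACAM7* (2.99), *CBX2* (2.94), *MFNG* (2.91), *GUCY2C* (2.76), *C2orf72* (2.45), *VSNL1* (2.38) and *MISP3* (2.37). *CEACAM7* and the keratin gene *KRT16* may share reads with close relatives, which makes their counts uncertain. The largest falls besides *TGFBR1* were *IGFBP1* (-3.58), the ferric reductase gene *CYBRD1* (-2.99; 101.9 to 12.9 CPM), *HSPA13* (-2.84), *CPD* (-2.79), *PLAT* (-2.75), *SKAP2* (-2.70), *KRT16* (-2.68), *PAQR3* (-2.61), *PBK* (-2.58), *ANO6* (-2.53) and *PSAT1* (-2.49). *CYBRD1*, *HSPA13*, *CPD*, *SKAP2*, *TGFBR1*, *PAQR3*, *PBK*, *ANO6* and *PSAT1* carry the sequence AACATTA or ACATTAA in their 3′ UTR, as did 50.8% of all genes that fell and had a 3′ UTR to search, against 16.9% of genes not called.

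SiCont replicate 2 stood apart from the other siCont libraries (chi-square per degree of freedom 29.5 and 35.2 against them, 8.82 between them) and decided the size of several of these changes. Without it *IGFBP1* stood at -1.08, *HSPA13* at -1.88, *PSAT1* at -1.32 and *GUCY2C* at 3.72. *CBX2* stood at 3.68 without siCont replicate 3 and *MFNG* at 3.67 without siCont replicate 1. *IGFBP1* lost its call without any one siBACH1 replicate (edgeR adjusted p = 0.116, 0.1 and 0.0996) and with limma-voom (log2 -2.27, adjusted p = 0.17), and *PSAT1* lost it without siBACH1 replicate 1 or 3 (edgeR adjusted p = 0.0664 and 0.0568). Limma-voom placed *CEACAM7* at 3.70.

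Antioxidant genes that NRF2 activates rose as a list. Of 29 measured, 19 rose, 4 fell and 6 did not pass, with 19 and 4 adjusted over the list alone. The list stood above other genes (camera adjusted p = 3.32e-17) and kept that call with an estimated correlation (adjusted p = 0.0257). Besides *GCLM*, *AKR1C2* (log2 2.28 ± 0.11), *TRIM16L* (2.52 to 11.8 CPM), *GPX2* (2.05 ± 0.12) and *AKR1B10* (1.73 ± 0.33) rose, and so did the quinone reductase *NQO1* (0.96 ± 0.12). The 4 that fell were *TXN*, its reductase *TXNRD1* (-1.05 ± 0.20), the cystine transporter *SLC7A11* (-1.26 ± 0.31) and the pentose phosphate enzyme *TALDO1* (-0.33), and all 4 carry one of the sequences above in the 3′ UTR, as do 4 members that rose, among them *AKR1C1* (2.02) and *GCLC* (1.52). Without siCont replicate 2 *SLC7A11* stood at -0.69 and *TXNRD1* at -0.74 (*TXN* -2.04). *SLC7A11* lost its call without siBACH1 replicate 1, 2 or 3 (edgeR adjusted p = 0.076, 0.0737 and 0.0612) and *TALDO1* without siBACH1 replicate 1 (0.0603). *AKR1C1*, *AKR1C2* and *AKR1C3* are near-identical, so reads may be shared among them.

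Of 23 heme and iron genes, 7 rose, 3 fell and 13 did not pass, with 8 and 5 adjusted over the list alone. The median log2 fold change was -0.03 while the mean was 0.33 and camera placed the list upwards (adjusted p = 0.00366, but adjusted p = 0.198 with an estimated correlation). *HMOX1*, the porphyrin transporter *ABCB6* (1.61), the iron exporter *SLC40A1* (1.16) and the ferric reductase *STEAP3* (1.05) rose, as did the ferritin chains *FTL* (1.04) and *FTH1* (0.95), which have many processed copies in the genome. *ABCB6* lost its call without siBACH1 replicate 2 or siCont replicate 1 (edgeR adjusted p = 0.0828 and 0.0604). *IREB2*, which encodes an iron-regulatory RNA-binding protein and carries a 3′ UTR match, fell by 1.48, and *HMOX2* fell by 0.76.

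Of 36 epithelial genes, 15 rose, 5 fell and 16 did not pass, with 18 and 6 adjusted over the list alone (camera adjusted p = 0.00641, upwards; adjusted p = 0.198 with an estimated correlation). *CDH1*, E-cadherin, rose from 108.8 ± 4.20 to 194.5 ± 6.86 CPM (SD, n = 3 each; log2 0.84 ± 0.07 SE, edgeR adjusted p = 7.18e-05), and the transcription factor gene *FOXA1* rose by 1.60 ± 0.24. *CDH1*, *FOXA1*, *CLDN3*, *CLDN4* and *PKP2* may have been picked by the study on these libraries, so their counts are not independent evidence, and without them the list lost its call (camera adjusted p = 0.131). The splicing regulator *ESRP2* rose by 1.07, while *KRT7* (-1.48) and the desmosomal cadherins *DSG2* (-1.18) and *DSC2* (-0.58) fell. Of 23 mesenchymal genes, 1 rose, 7 fell and 15 did not pass, with 1 and 8 adjusted over the list alone (camera adjusted p = 0.00366, downwards; adjusted p = 0.198 with an estimated correlation). *TGFBR1* and *SNAI2* were among the falls, vimentin (*VIM*) fell by 0.64, and *THBS1*, thrombospondin 1, rose by 2.07 ± 0.26. *TGFBR1*, *DSG2*, *DSC2* and *PKP2* carry a match in the 3′ UTR, and *SNAI2*, *AXL* and *VIM* do not.

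**Figure D2:**
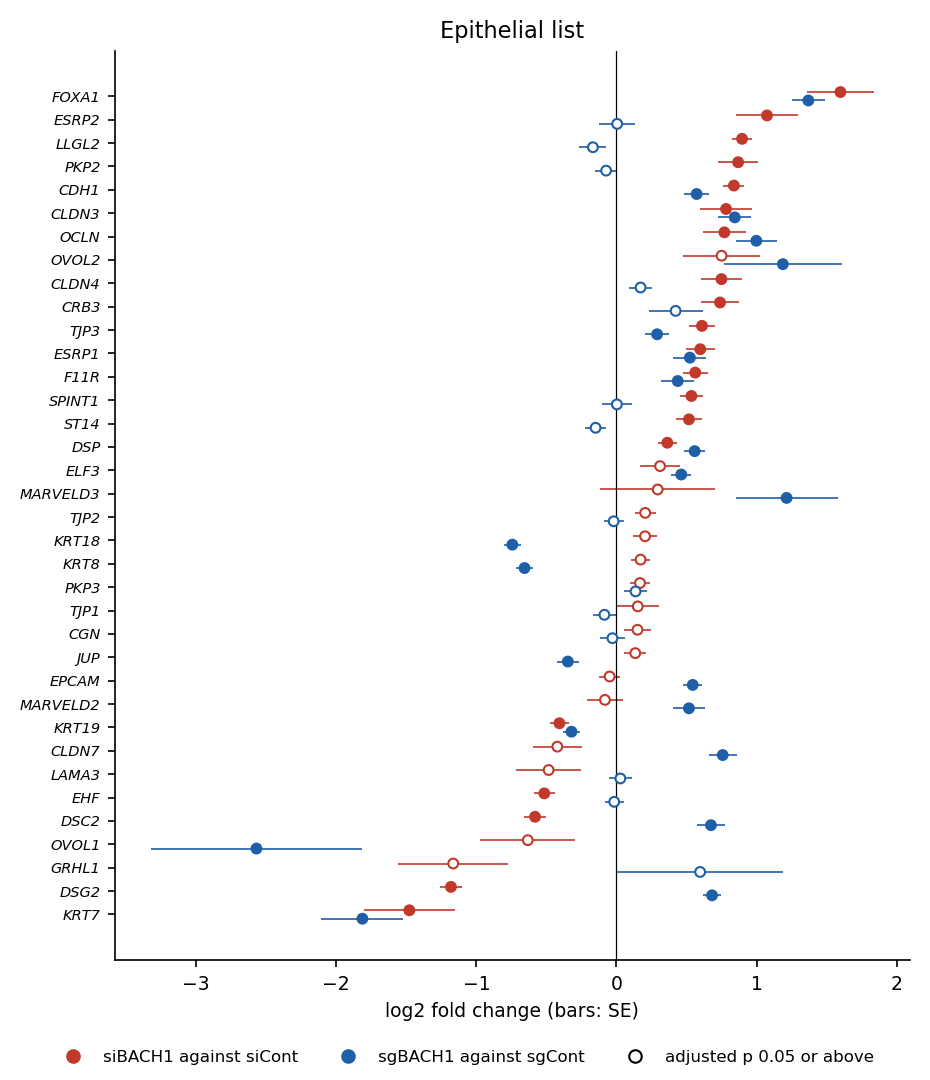
Log2 fold change (horizontal axis; bars, SE) of each tested gene of the epithelial list in siBACH1 against siCont (red) and sgBACH1 against sgCont (blue), filled where the edgeR adjusted p was below 0.05. *CDH1* and *FOXA1* rose in both experiments, while *DSG2* fell by 1.18 with the siRNA and rose in the knockout.

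Of 20 glycolysis genes, 1 rose and 8 fell, with 1 and 9 adjusted over the list alone (camera adjusted p = 0.00892; adjusted p = 0.433 with an estimated correlation), among them *PFKP* (-1.72), *ALDOC* (-0.81) and *HK1* (-0.78), of which *PFKP* carries a 3′ UTR match. Of 19 hypoxia genes, 1 rose and 8 fell over all genes and adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.744 with an estimated correlation), led by carbonic anhydrase *CA9* (-2.07). Of 22 genes of the integrated stress and unfolded protein responses, 10 fell and none rose, with 12 and 0 adjusted over the list alone (camera adjusted p = 0.00641; adjusted p = 0.744 with an estimated correlation). *ASNS* at -2.07 did not pass (edgeR adjusted p = 0.08), whereas *DNAJB9* (-2.28), *DDIT4* (-1.99) and the folate enzyme *MTHFD2* (-1.79) fell. Without siCont replicate 2 they stood at -1.60, -0.92 and -0.63, and without siBACH1 replicate 1, 2 or 3 *DDIT4* (edgeR adjusted p = 0.0855, 0.0811 and 0.083) and *MTHFD2* (0.137, 0.125 and 0.11) lost their calls. SiCont replicate 2 was high in these genes: *ASNS* stood at 1051 CPM there against 116.2 and 106.6 in the other siCont libraries, and the hypoxia list summed to 1525 CPM against 1200 and 1059. The stress response and hypoxia lists kept their calls without that library (camera adjusted p = 0.00985 and adjusted p = 0.0476). Of 9 neighbours of *BACH1* on chromosome 21, 6 fell, with 7 adjusted over the list alone (camera adjusted p = 0.00366; adjusted p = 0.198 with an estimated correlation). The superoxide dismutase gene *SOD1* (-1.49) and *USP16* (-0.78) led them, and both carry a match in the 3′ UTR. Without genes carrying a match the antioxidant (camera adjusted p = 6.61e-24), heme and iron (0.000291), epithelial (0.00104), mesenchymal (0.0011), stress response (0.0011), glycolysis (0.00847) and hypoxia (0.0129) lists kept their calls, and the list of neighbours had too few members left. A match here means AACATTA or ACATTAA alone, and genes with related sequences were not left out. Genes that changed because a gene with a match fell would also remain. A kept call therefore does not exclude an effect that began with the matched genes.

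The knockout comparison asks the same question in cells carrying the guide against *BACH1*. *HMOX1* rose from 8.99 ± 2.48 to 474.1 ± 32.5 CPM (SD, n = 3 each; 52.0-fold, log2 5.70 ± 0.13 SE, edgeR adjusted p = 2.93e-20) and *GPX2*, a glutathione peroxidase, from 3.84 to 202.1 CPM (log2 5.71 ± 0.13). The gel-forming mucin *MUC5B* rose from 1.42 to 77.5 CPM (log2 5.74 ± 0.18) and the trefoil peptides *TFF1* and *TFF3* by 6.03 ± 0.58 and 5.19 ± 0.22. *CFI*, a protease gene, fell by 5.80 ± 0.65. *CD74*, the invariant chain of major histocompatibility complex class II, fell from 575 counts over the sgCont libraries to 0 over sgBACH1, at least 205-fold lower against 3 counts over the group, a floor that covers counting error only.

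Of 14469 genes tested by edgeR, 3407 changed in sgBACH1, 1629 upwards and 1778 downwards (1523 and 1495 without sgCont replicate 3), and 446 rose and 459 fell by more than 1 on the log2 scale. The groups did not overlap in 5283 genes (36.5%; chance gives 10%). Without genes lying in the chromosome blocks described below 2754 genes were called, and 2135 when genes carrying a 3′ UTR match were left out as well, both fits added after seeing the data. The other large rises were the potassium channel subunit *KCNE3* (0 against 241 counts, at least 75.0-fold higher against 3 counts over the group), *RIMKLA* (log2 7.15), the hyaluronan-binding *CEMIP* (6.02; 2.96 to 190.4 CPM), *SYT13* (5.42), *IQGAP2* (5.10), *CEACAM5* (4.99) and *HYKK* (4.99). Other large falls were *ANKRD1* (-6.18), *HAVCR1* (-5.51), *DMBT1* (-5.25), *SLC14A1* (-5.01), *PTPRM* (-4.87), the class II chain *HLA-DRA* (-4.75), *GASK1B* (-4.67), *FAT4* (-4.61) and *NMUR2* (-4.48). Genes with any count numbered 21454, 20780 and 22503 in sgCont replicates 1 to 3, fewer than in sgBACH1 (23716, 23452 and 25502). Depth alone did not set this, since sgCont replicate 1 held more counts than sgBACH1 replicate 2. How far it bears on rises from counts near the floor in sgCont was not tested. Several sizes rest on single libraries. *RIMKLA* stood at 6.52 and 8.36 without sgCont replicate 1 or 3 and *TFF1* at 5.39 without the former, while without the latter its sgCont libraries stood at 0 counts and the fitted 10.56 is no size. Without sgBACH1 replicate 1 *CFI* stood at -7.61, *HLA-DRA* at -5.34 and *FAT4* at -5.53. Without sgBACH1 replicate 3 *DMBT1* stood at 0 counts in sgBACH1, so the fitted -9.18 is no size, *CFI* stood at -5.14, *HLA-DRA* at -4.10 and *FAT4* at -4.00, and *GASK1B* stood at -5.42 without replicate 2. Limma-voom placed *TFF1* at 7.12, *DMBT1* at -6.04 and *FAT4* at -5.35.

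Changes in the knockout also followed chromosome position. Of 143 windows of about 100 neighbouring tested genes, 6 had a median log2 fold change above 0.3 and 7 one below -0.3, against 0 in the siRNA comparison. The moved windows lay on chromosome X from 56563639 to 155943769 (GRCh38; median 0.70; 143 genes rose and 6 fell), on chromosome 19 from 43827292 to 58599801 (median 0.39), on chromosome 3 from 149369022 to 180982753 (median -0.41), on chromosome 12 from 52897187 to 57132139 (-0.351) and from 120640552 to 133214831 (-0.333), and on chromosome 16 from 46407 to 28874212 (-0.424; 10 rose and 146 fell) and from 75536744 to 90044975 (-0.444). Between these pieces the windows of chromosome 12 stood at -0.172, -0.29 and -0.144 and those of chromosome 16 at -0.205, 0.237 and -0.064. Neighbours on chromosome 12 (-0.29, 4 rose and 32 fell) and chromosome 3 (-0.285, 2 rose and 32 fell) also lay beyond the largest median of shuffled gene orders, 0.249. In windows on chromosomes 11 (-0.185 and -0.186) and 20 (0.215 and 0.217) calls went mostly 1 way. Others did so too, among them windows on chromosome 9 (0.209, 27 rose and 3 fell) and chromosome 22 (-0.081, 0 rose and 14 fell). The windows beyond 0.3 hold 571 of the 3407 called genes (a share of 0.168) and none of the genes named for their size of change above. Inside these windows 45.7% of tested genes were called, against 21.6% outside.

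**Figure D3:**
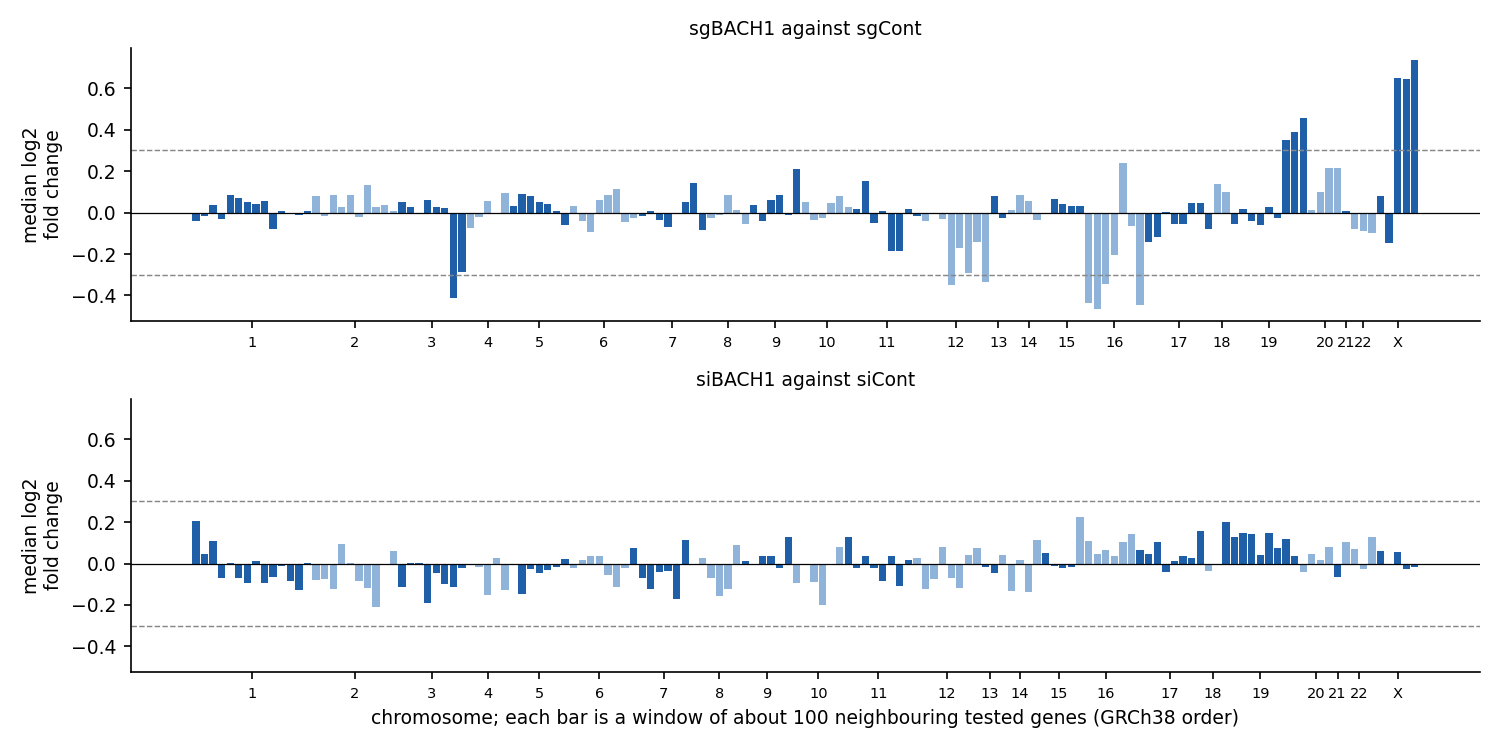
Median log2 fold change (vertical axis) of windows of about 100 neighbouring tested genes along the chromosomes (horizontal axis, shades alternate by chromosome) in sgBACH1 against sgCont (top) and siBACH1 against siCont (bottom), with dashed lines at 0.3 and -0.3. In the knockout comparison 13 of 143 windows lie beyond the lines, on chromosomes 3, 12, 16, 19 and X, and in the siRNA comparison 0 do.

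The antioxidant list rose in the knockout too. Of 29 measured genes, 20 rose and none fell, with 21 and 0 adjusted over the list alone (camera adjusted p = 3.45e-40; adjusted p = 0.00223 with an estimated correlation). *GPX2*, *GCLM* (log2 3.60 ± 0.16), *AKR1B10* (2.92 ± 0.21) and the transporter *ABCC2* (2.41 ± 0.09) rose most, and *NQO1* rose by 1.09 ± 0.06. *TXN* rose by 0.65 ± 0.08 and *SLC7A11* by 1.01 ± 0.08. Of 23 heme and iron genes, 8 rose and 5 fell, with 10 and 5 adjusted over the list alone (camera adjusted p = 7.22e-08; adjusted p = 0.0283 with an estimated correlation). *FTH1* (1.86 ± 0.07), *FTL* (1.30) and *SLC40A1* (1.12) rose and *STEAP3* fell by 0.98, *FTL* lying in the chromosome 19 block.

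Of 24 pancreatic ductal and mucosal genes, 13 rose and 7 fell, adjusted over all genes and adjusted over the list alone (camera adjusted p = 3.33e-19; adjusted p = 0.00786 with an estimated correlation). Besides *MUC5B*, *TFF1*, *TFF3* and *CEACAM5*, *REG4* (3.15), *TFF2* (2.98) and *CEACAM6* (2.52) rose, and carbonic anhydrase *CA2* (-1.33) and *MUC13* (-0.97) fell. The CEACAM and MUC5 genes have close relatives that may share reads.

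Of 36 epithelial genes, 16 rose, 6 fell and 14 did not pass, the same numbers as adjusted over the list alone (camera adjusted p = 0.0169, upwards; adjusted p = 0.138 with an estimated correlation). *CDH1* rose from 87.2 ± 1.37 to 129.7 ± 10.8 CPM (SD, n = 3 each; log2 0.57 ± 0.09 SE, edgeR adjusted p = 2.13e-05) and *FOXA1* by 1.37 ± 0.12. Occludin (*OCLN*, 1.00) rose, while *KRT7* (-1.81) and the most abundant members, *KRT8* (-0.66) and *KRT18* (-0.74) in the chromosome 12 blocks, fell. The summed CPM of the list was lower in sgBACH1 (17422, 18886 and 19017) than in sgCont (23376, 23371 and 24581). *OVOL1* (-2.57) fell most but lost its call without sgBACH1 replicate 1, 2 or 3 (edgeR adjusted p = 0.0921, 0.092 and 0.0706) or sgCont replicate 3 (0.0522). Without the 5 genes the study may have picked the list lost its call (camera adjusted p = 0.155), as it did without sgCont replicate 2 (0.0581), whereas without genes in the moved blocks it kept it (0.000537). Of 20 mesenchymal genes, 3 rose and 10 fell, the same numbers as adjusted over the list alone (camera adjusted p = 3.5e-05, downwards; adjusted p = 0.0418 with an estimated correlation). The fibronectin receptor chain *ITGA5* (-2.96, in the chromosome 12 block), *TGFB2* (-2.18), tenascin C (*TNC*, -1.18) and the receptor kinase *AXL* (-0.87) fell. The summed CPM of the mesenchymal list went the other way, higher in sgBACH1 (6977, 7313 and 7352) than in sgCont (6660, 6870 and 6748).

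Of 23 cholesterol synthesis genes, 13 rose and 1 fell, with 15 and 1 adjusted over the list alone (camera adjusted p = 0.000174; adjusted p = 0.0445 with an estimated correlation), among them *NSDHL* (1.16, chromosome X block), *ACAT2* (0.83), *IDI1* (0.63) and *HMGCS1* (0.58). Of 20 glycolysis genes, 8 rose and 2 fell over all genes and adjusted over the list alone, with a median of 0.005 (camera adjusted p = 0.015; adjusted p = 0.437 with an estimated correlation), led by the glucose transporter *SLC2A1* (1.58) and *PGK1* (0.94, chromosome X block). Of 25 p53 and DNA damage genes, 9 rose and none fell, likewise adjusted over the list alone (camera adjusted p = 0.022; adjusted p = 0.138 with an estimated correlation), led by *GDF15* (3.24), while *CDKN1A* at -0.29 did not pass. Of 29 ribosomal protein genes, 10 rose and 3 fell, with 11 and 3 adjusted over the list alone (camera adjusted p = 0.0169; adjusted p = 0.526 with an estimated correlation; 0.0581 without sgCont replicate 2), led by *RPS4X* (1.08, chromosome X block). Without genes in the moved blocks the last 3 lists lost their calls (camera adjusted p = 0.0664, 0.0664 and 0.0788), and the antioxidant (1.9e-47), heme and iron (3.48e-08), ductal (8.04e-25), mesenchymal (0.000314) and cholesterol (0.000314) lists kept theirs.

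The overlap of both comparisons asks which genes respond to both ways of lowering BACH1. Among genes called in both, *HMOX1* and *GCLM* changed most by the smaller of the 2 values, followed by *C2orf72* (2.45 with the siRNA, 2.40 in the knockout), *KRT16* (-2.68, -2.16), *GPX2* (2.05, 5.71) and the aldo-keto reductases *AKR1C2* (2.28, 2.01) and *AKR1C1* (2.02, 1.99). *FAM83A* (-1.90, -2.26), *IGSF9* (1.89, 1.87), *LDLRAD4* (-1.86, -3.75), *FABP3* (-1.82, -2.50) and the BMP antagonist *NOG* (-2.02, -1.81) followed. The siRNA value of *LDLRAD4*, which carries a 3′ UTR match, lost its call without siBACH1 replicate 3 (edgeR adjusted p = 0.0689). That of *FABP3* lost it without any one siBACH1 replicate (edgeR adjusted p = 0.12, 0.112 and 0.0816) and with limma-voom (0.084), and stood at -1.08 without siCont replicate 2.

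Of 13845 genes tested in both, 320 rose in both, where independent lists would share 179.8 (odds ratio 2.23, one-sided Fisher's exact p = 5.59e-28), and 347 fell in both, against 229.3 (odds ratio 1.79, exact p = 1.53e-17). Genes called in opposite directions numbered 220 (risen with the siRNA) and 268 (fallen with it), against 189.1 and 217.9 of independent lists (odds ratios 1.22 and 1.32, exact p = 0.00694 and 8.82e-05), so these too were more than independent lists would share. Independent lists may therefore be too low a baseline for genes called the same way as well. The exact tests also treat genes as independent, which they are not. The 667 genes called in the same direction fell to 427 and 438 without siBACH1 replicate 1 or 3. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.119 and Spearman rho = 0.0652. Among 10445 genes without a 3′ UTR match and outside the moved blocks, 204 rose in both against 88.8 of independent lists (odds ratio 3.09) and 202 fell in both against 98.5 (odds ratio 2.64). There 92 and 116 were called in opposite directions, against 89.9 and 97.2 (odds ratios 1.03 and 1.25).

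**Figure D4:**
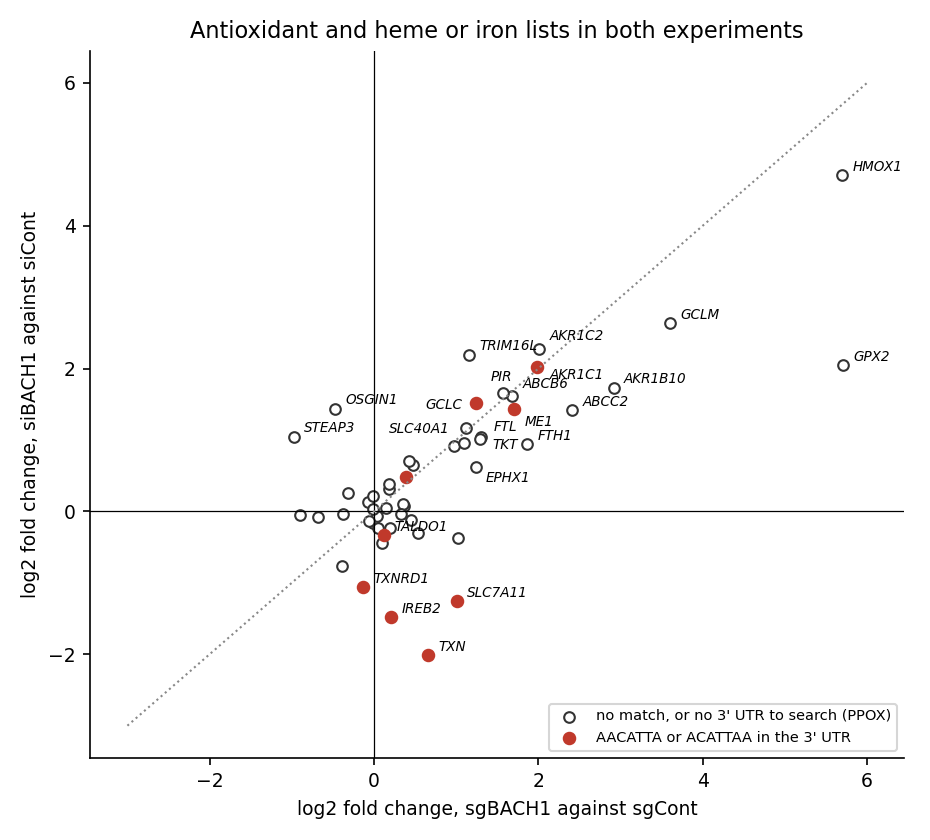
Log2 fold change in sgBACH1 against sgCont (horizontal axis) and in siBACH1 against siCont (vertical axis) of each tested gene of the antioxidant and of the heme and iron lists, red where the 3′ UTR holds AACATTA or ACATTAA, with a dotted line of equal values. *HMOX1*, *GCLM* and *GPX2* lie at the upper right, and *TXN* and *SLC7A11* rose in the knockout and fell with the siRNA.

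The test of the difference asks where the responses to the siRNA and to the guide were unlike. *MUC5B* differed by -8.04 ± 0.32 and *TFF1* by -6.56 ± 0.91 (siRNA minus knockout log2 response, SE, 12 libraries). *CFI* differed by 4.82 ± 0.74. Among antioxidant genes *TXN* differed by -2.67 ± 0.12 (edgeR adjusted p = 1.38e-10), *SLC7A11* by -2.26 (9.48e-05) and *TXNRD1* by -0.92 (0.0041). *HMOX1*, up in both, differed by -0.99 (0.00141).

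Of 15644 genes tested, 3687 differed, 1653 upwards and 2034 downwards, and 2015 differed without genes that carry a match or lie in a block. Of the mesenchymal genes, *TGFBR1* (-2.84) and *SNAI2* (-2.08) differed downwards and *THBS1* (2.93) and *ITGA5* (2.37) upwards, with 5 up and 7 down of 23 and no call for the list (camera adjusted p = 0.954), whose median was -0.14 and mean 0.02. *CDH1* at 0.27 (edgeR adjusted p = 0.0867) and *FOXA1* at 0.23 (0.604) did not pass the test of the difference, which does not show equal responses. *BACH1* differed by -2.67 ± 0.18. The siRNA and knockout libraries come from separate tables with different handling of the cells, so the test compares the responses as deposited, each against its own controls.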

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

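No test in this part was chosen after its result was seen, and the tests of gene lists between the experiments were not in the original plan. The responses to the siRNA and to the knockout differed in 3687 of 15644 genes by edgeR's test of the difference over 12 libraries. Of 100 splits of the libraries within each experiment, 1, the real split, gave as many. The highest of the others gave 1086 and their median was 0. A split that mixes the groups of an experiment puts their difference into the spread within groups, which lowers its count. Within each experiment alone, every such split called 0 genes. These splits also do not ask whether the responses were equal, so whether the count arose by chance cannot be told apart with them.

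Many of the genes with the largest differences are among those that changed most in the knockout. Given as siRNA minus knockout on the log2 scale, *CD74* differed by 11.11 ± 1.51 (SE), a fitted value that is no bound because sgBACH1 stood at 0 counts. *CFI* differed by 4.82 ± 0.74, *DMBT1* by 5.56 ± 0.90, the protocadherin *FAT4* by 5.54 ± 1.24 and *FAM171A1* by 4.55 ± 0.48. Downwards, *MUC5B* differed by -8.04 ± 0.32, *TCIM* by -7.22 ± 1.44, *CEMIP* by -6.76 ± 0.45, *TFF1* by -6.56 ± 0.91, *SYT13* by -6.48 ± 0.42 and *IGFBP2* by -6.44 ± 1.19, the last a fitted value with sgCont at 0 counts.

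For some of these genes the 2 control groups themselves stood far apart. The siCont and sgCont means were 0.11 and 22.4 CPM for *FAT4* and 0.94 and 21.8 CPM for *FAM171A1*. They were 0.62 and 11.7 CPM for *CD74* and 38.5 and 0 CPM for *IGFBP2*, but closer for *CEMIP* (3.93 and 2.98 CPM). *FAT4*, *FAM171A1* and *CD74* thus had little room to fall with the siRNA. Single libraries set the size of several of these differences. *TCIM* stood at -4.83 without siCont replicate 2, -6.60 without sgCont replicate 1 and -8.13 without sgCont replicate 3, and *TFF1* at -5.88, -5.93 and -11.09 without the same libraries. *DMBT1* stood at 9.54 without sgBACH1 replicate 3. The values -11.09 for *TFF1* and 9.54 for *DMBT1* are fits with a group at 0 counts and no sizes. *CFI* stood at 6.62 and 4.17 without sgBACH1 replicates 1 and 3. *FAT4* stood at 7.12 without siCont replicate 1 and 6.46 without sgBACH1 replicate 1. *CD74* stood at 10.30 without siBACH1 replicate 2 and 12.40 without siCont replicate 1. Limma-voom gave 9.90 for *CD74*, 6.33 for *DMBT1*, 6.48 for *FAT4*, -6.46 for *TCIM*, -7.45 for *TFF1* and -4.43 for *IGFBP2*, and DESeq2 gave -5.80 for *IGFBP2*.

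Of the fixed lists, 8 responded differently to the siRNA than in the knockout, and all 8 stood lower with the siRNA. These tests were not repeated without genes that carry a 3′ UTR match or lie in a moved block. Among members with large differences *TXN*, *SLC7A11*, *PFKP*, *MSMO1*, *STARD4*, *SOD1* and *USP16* carry a match, and *NSDHL* lies in the chromosome X block. For *GPX2*, *SLC2A1*, *IDI1* and *MUC5B* neither holds. Camera gave adjusted p = 0.0066 for the antioxidant list (2 genes higher and 10 lower of 29; adjusted p = 0.0852 with an estimated correlation). It gave adjusted p = 0.000379 for the ductal list (6 higher and 9 lower of 24; adjusted p = 0.0341 with an estimated correlation). For glycolysis it gave adjusted p = 0.000379 (1 higher and 9 lower of 20) and for hypoxia adjusted p = 0.0015 (1 higher and 7 lower of 19), with adjusted p = 0.24 and adjusted p = 0.451 at an estimated correlation. The stress response list had adjusted p = 0.00261 (0 higher and 15 lower of 22) and the cholesterol list adjusted p = 0.00779 (0 higher and 8 lower of 23), with adjusted p = 0.603 and adjusted p = 0.605 at an estimated correlation. The p53 list had adjusted p = 0.0249 (1 higher and 9 lower of 25) and the chromosome 21 neighbours adjusted p = 0.0336 (0 higher and 4 lower of 9), with adjusted p = 0.337 and adjusted p = 0.226 at an estimated correlation. SiCont replicate 2 was high in the stress response list, which summed to 5681 CPM there against 2908 and 3097 in the other siCont libraries, and in the p53 list (1171 against 716 and 745 CPM), and low in the cholesterol list (2343 against 3363 and 3408 CPM).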

How the results depend on the processing

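Fits with GC and length offsets and fits without genes carrying a 3′ UTR match or lying in moved blocks were chosen after seeing the data, and all other alternatives here were planned. Over all alternatives 140 counts and *BACH1* values stayed within 1.5 times the reported count or kept their call, and 13 counts did not. Of 78 results of genes chosen by rule, 4 lost a call in 11 of 1498 values and 0 changed sign. List members named besides them are not in this count, and several lost calls without single libraries, as given beside them. There is no value for *IGFBP1* from DESeq2, which gave it no adjusted p. Of list results, 168 kept their call and 20 did not. Other planned settings gave 3196 to 4572 genes for the siRNA, 3356 to 4201 for the knockout, 3513 to 4669 for the difference and 654 to 969 changed the same way in both.

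Without genes carrying a 3′ UTR match the siRNA comparison called 2071 genes. Without genes with a match or in a moved block it called 1932, the knockout 2135 (2754 without block genes alone) and the difference 2015, and 406 changed the same way in both, with fewer genes tested by construction. With an estimated correlation 1 list was called for the siRNA and 5 for the knockout, and fry called 14 for the knockout. For the siRNA the hypoxia and stress response lists lost their calls with fry (fry adjusted p = 0.0987 and 0.197). Fry does not compare a list with other genes.

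Leaving out each library in turn gave 2002 to 5121 genes for the siRNA, the lowest without siBACH1 replicate 1 (2078 and 2096 without siBACH1 replicates 2 and 3) and the highest without siCont replicate 2, and 427 to 957 changed the same way in both. The latter fell to 427 and 438 without siBACH1 replicates 1 and 3. Without siCont replicate 2, 3413 of the 3481 genes were still called. Leaving out libraries gave 2500 to 3586 genes for the knockout, 2960 to 3990 for the difference, 8 to 12 lists for the siRNA, 7 to 10 for the knockout, and *BACH1* at -3.26 to -2.94 and -0.54 to -0.42. Apart from fewer libraries, the cause was not tested.

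The labels number replicates alike. Deviations of same-numbered libraries correlated at 0.0561, 0.0397 and 0.0191 in the siRNA experiment and -0.0169, 0.0516 and 0.0404 in the knockout. Differently numbered libraries correlated at -0.0478 to 0.0106 with the siRNA and at -0.0623 to 0.0317 in the knockout. All values are small, but with the siRNA every same-numbered pair lay above the others. Pairing by number is thus neither shown nor excluded. With the replicate block 3196, 3530 and 3513 genes were called for the siRNA, the knockout and the difference, *IGFBP1* stood at -2.41 with the siRNA and the difference for *TCIM* was -6.12. Scaling moved the median log2 fold change of all genes by at most 0.034. At 13099706 to 21478886 counts per library, genes near the filter's minimum were measured least precisely, and changes of 1.5 fold were mostly missed in the simulation of the difference.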

Other observations

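The tests of knockout changes inside and outside the moved chromosome blocks and against their neighbours, the offsets for GC content and length, and the counts without genes carrying a 3′ UTR match or lying in those blocks, were chosen after the results were seen. Chemokine and interferon genes moved in part with the siRNA. *CXCL3* (log2 1.54 ± 0.20, SE), *CXCL1* (1.34) and *CXCL5*, which attract neutrophils, rose, and the NF-kB inhibitor *TNFAIP3*, which carries a 3′ UTR match, fell by 0.80, with 4 up and 2 down of 18 NF-kB and cytokine genes, also adjusted over the list alone (camera adjusted p = 0.203). Of 28 interferon-stimulated genes, 2 rose and 8 fell, with 2 and 9 adjusted over the list alone (camera adjusted p = 0.0915), among them *IFIT1* (-1.71), *ISG15* (-1.31) and *IFIT2* (-1.27), of which *ISG15* carries no 3′ UTR match. In the knockout 2 of 16 cytokine genes rose and 5 fell, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.107; *CXCL3* 1.80, *TNFAIP2* -1.66, *TNFAIP3* -1.25). There 3 of 25 interferon genes rose and 4 fell, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.75; *ISG20* -1.14, *OAS1* 0.58). The heat shock gene *HSPA6* fell by 2.98 with the siRNA (-3.65 without siBACH1 replicate 3), with 1 up and 5 down of 16, also adjusted over the list alone (camera adjusted p = 0.307), and *HSPB1* fell by 0.85 in the knockout, with 1 up and 3 down, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.216). Among partners and relatives of BACH1, *NFE2L2*, which encodes NRF2, rose in the knockout (0.45 ± 0.09), and *NFE2L3* fell there by 1.95. That list gave 2 up and 0 down of 7 with the siRNA and 2 up and 3 down in the knockout, also adjusted over the list alone, and camera called it in neither (adjusted p = 0.386 and 0.268). Its knockout median was 0.05 and its mean -0.33.

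In the knockout hypoxia genes rose in 6 and fell in 2 of 19 cases, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.06), led by *ANGPTL4* (5.47 ± 0.81; 6.32 without sgCont replicate 3), a secreted lipase inhibitor. Stress response genes rose in 6 and fell in 2 of 22, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.221), and of 9 chromosome 21 neighbours none passed edgeR, with *N6AMT1* at -0.54 (adjusted p = 0.228; camera adjusted p = 0.93). With the siRNA 10 of 23 ductal genes rose and 3 fell, with 11 and 3 adjusted over the list alone; the median was 0.26, the mean -0.01 and camera pointed upwards (adjusted p = 0.0915; *MUC5B* -2.31). Cholesterol genes fell in 6 and rose in 0 of 23 cases, also adjusted over the list alone (camera adjusted p = 0.464; *MSMO1* -1.40, with a match), and p53 genes rose in 2 and fell in 4 of 25, with 2 and 7 adjusted over the list alone (camera adjusted p = 0.386; *TP53INP1* -2.13, with a match, whose call was lost without siBACH1 replicate 2 or 3, adjusted p = 0.0615 and 0.0543). Cell cycle genes gave 7 up and 4 down of 32 with the siRNA, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.203; *RRM2* -0.55, with a match), and 3 up and 2 down in the knockout, also adjusted over the list alone (camera adjusted p = 0.75; *PLK1* -0.64, in the chromosome 16 blocks). Respiratory chain genes gave 1 up and 1 down of 28, or 0 and 1 adjusted over the list alone, and 6 up and 3 down, also adjusted over the list alone (camera adjusted p = 0.702 and 0.327; *NDUFA1* 1.14 in the knockout, in the chromosome X block). Ribosomal protein genes rose in 6 of 29 cases with the siRNA, also adjusted over the list alone (camera adjusted p = 0.0799; *RPL13A* 0.44). Histone genes gave 2 up of 10 with the siRNA and 3 down in the knockout, also adjusted over the list alone (camera adjusted p = 0.422 and 0.225). Mitochondrially encoded genes gave none past edgeR with the siRNA (*MT-ND1* 0.18, adjusted p = 0.106) and 1 up and 2 down of 13 in the knockout (camera adjusted p = 0.464 and 0.847). Abundant noncoding RNAs gave none of 11 with the siRNA (*RNU5A-1* -0.73, adjusted p = 0.0704) and 2 up and 2 down of 12 in the knockout (camera adjusted p = 0.849 and 0.75), the latter 2 lists with the same counts adjusted over the list alone.

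Lists of other cell types had too few tested members for a list test. *LYZ*, lysozyme, of the blood and endothelium list, rose in the knockout from 59.4 ± 8.62 to 733.0 ± 72.3 CPM (SD, n = 3 each; log2 3.62 ± 0.10 SE, edgeR adjusted p = 1.19e-18) and stood at -0.32 with the siRNA. *LUM*, lumican, of the fibroblast list, fell by 1.34 ± 0.10 in the knockout. Of the acinar and endocrine list, *BHLHA15* stood at -0.40 with the siRNA and -0.44 in the knockout without a call.

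Genes that fell with the siRNA shared a 3′ UTR sequence. Adjusted for 3′ UTR length and GC content and for mean CPM, the 1538 genes with AACATTA stood 0.425 lower on the log2 scale than others. This coefficient over its standard error was -26.5, 7.11 times the most negative score of any 7-base sequence in the knockout comparison. Without adjustment, genes with AACATTA or ACATTAA fell in 36.3% of cases against 9.5% without. GC content and length are argued against as the cause of the number of fallen genes, since offsets for them left it at 0.908 of its value. Of all 3481 calls, 2808 were kept with the offsets. The 7-base scores were not computed with offsets, so this does not bear on single genes or on the shared sequence. The *BACH1* transcript itself holds AACATTA 4 times. A given 7-base sequence occurs at least once in its 5769 bases with a chance of 0.297, taking all bases as equally frequent. A candidate explanation is that the siRNA also acted on other transcripts through matches to its seed, but its sequence is not given in the sources used here. Falls of genes with a match, such as *TXN*, *SLC7A11* and *TGFBR1*, may thus be unrelated to BACH1, while the fallen genes without a match stay open, and *SLC7A11* stood at -0.69 without siCont replicate 2. A match means only AACATTA or ACATTAA, the 2 lowest scores in these same data. Related sequences also scored low with the siRNA (CATTAAT -14.1, ACATTAT -12.0, GACATTA -11.6), against -3.73 at the lowest in the knockout. They overlap the 2 sequences, so the scores are not independent. Leaving out genes with a match therefore need not remove every such gene. Of the 10 splits of the libraries 1, the real one, called as many as 3481 genes and the highest of the others 0, but the splits are too few for a share under 0.05.

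Genes that changed in the knockout lay partly in chromosome blocks. The moved windows hold a share of 0.168 of the called genes, between the bounds set for and against copy number as the whole cause, so that explanation cannot be told apart for the whole count. Where windows were chosen by every second gene, a share of 0.932 of the called genes among the others changed the way of their window, which is consistent with copy number differences between the sgBACH1 and sgCont populations inside the blocks. Outside, a share of 0.623 of the called genes changed the way of their nearest 10 tested genes on each side, between the bounds of 0.8 and 0.6 set for and against, so copy number cannot be told apart there by direction, and some windows outside moved by less than 0.3. By size, a share of 0.199 of all called genes had such neighbours that moved the same way by at least 0.5 times as much. It was 0.708 inside the blocks and 0.095 outside. For most calls the neighbours at that width thus moved by less than this or the other way. By direction alone most calls went with their neighbours, 0.935 inside the blocks and 0.623 outside. With 2 neighbours on each side the share by size was 0.291 (0.632 inside the blocks, 0.221 outside). The share over all calls lay above the bound of 0.25 set against copy number as the cause of most calls. The share that chance alone would give was not measured, so this value decides nothing and narrow segments stay open. GC content and length are argued against as the cause of the number of calls, since offsets left 1.04 times as many and kept 3212 of the 3407. Other differences between separately selected cell populations, and loss of BACH1 itself, stay open inside and outside the blocks, and the 10 splits of the libraries, of which 1, the real one, gave as many genes (3407 against 0 for the highest other), are too few for a share under 0.05.

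Genes called the same way in both experiments numbered 667. Of 100 splits within each experiment 1, the real split, gave as many, and the highest of the others gave 0. Every mixed split called 0 genes by edgeR in its own experiment and was bound to share 0, so whether the lists met by chance cannot be told apart with these splits. Genes called in opposite directions, 220 and 268, also exceeded independent lists. Without genes that carry a match or lie in a block the refitted comparisons shared 406 called genes, and 92 and 116 were called in opposite directions, against 89.9 and 97.2 of independent lists (exact p = 0.422 and 0.022). A response to lower BACH1 is a candidate explanation for genes such as *HMOX1*, *GCLM* and *GPX2*, as a hypothesis that a rescue experiment, not analysed here, would test.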
